A study of Mus musculus with 36 samples.

How the data were processed

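The study measured messenger RNA in fresh-frozen kidney cortex and medulla of Balb/c mice 24 h after injection of 0, 1.3, 3.6, 14, 45 or 140 MBq of 177Lu-octreotate. Each tissue and activity is represented by 3 arrays, so there are 12 groups and 36 arrays, and the groups follow the sample titles. Per the labels, total RNA was extracted with a column kit for lipid-rich tissue, checked on a Bioanalyzer and labelled with biotin for Illumina bead arrays. The deposited signal table holds linear probe intensity values that carry no background subtraction and no normalisation between arrays. The deposited detection p-value beside each intensity, per the file headers, gives the share of negative control beads with at least that signal, in 798 steps. The deposited series table holds a second set of linear intensities, which the authors normalised between arrays by a method not given in the sources used here, and whose sorted values are closely alike on all arrays. It was used as an alternative setting.

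The signals covered 25697 probes, 7 of them outside the series table. Of these, 23974 carried 1 gene symbol, 0 carried several and 1723 none, which gave 16593 symbols. Symbols were compared with a RefSeq table of the mouse genome, used for names only, and 0 were replaced. Between 12152 and 13319 probes per array had a detection p under 0.05. Signals were background-corrected with negative controls inferred from the detection p, quantile-normalised with an offset of 16 and taken to log2 by neqc of limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for tables and matplotlib 3.10.9 for figures. A probe was kept where its detection p was under 0.05 on at least 3 arrays of the fit, and each gene was represented by its probe with the highest mean signal. Unnamed probes were kept under their own identifiers.

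Each tissue was fitted apart with limma (lmFit and eBayes) on its 18 arrays in 6 groups, with 12 residual degrees of freedom. Each activity was compared with 0 MBq, and a moderated F test asked for any difference among the 6 groups. A slope on log2 activity was fitted to the 15 treated arrays (13 residual degrees of freedom) and is given per doubling of activity. Cortex and medulla were compared at 0 MBq, and the tissue by activity interaction was tested, in a fit of all 36 arrays with 24 residual degrees of freedom. The p-values were adjusted by Benjamini and Hochberg's method within a comparison, and a gene was called at an adjusted p under 0.05. Errors after ± are limma's standard errors unless SD is written. A gene undetected on every array of a group is given a bound, computed from the detection limit, in place of its fitted change.

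Gene lists, 41 in number, were written from general knowledge of kidney cell types and of radiation responses. They were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over all lists of a comparison. Members were also counted after adjustment over the list alone. Genes are named by a fixed rule: the 5 largest rises and 5 largest falls of each activity (10 and 10 at 140 MBq) among called genes whose 3 treated arrays all lie beyond the 3 controls, a separation that chance gives 10% of genes. The rule adds the 5 genes each way with the smallest p of a trend, the 10 with the smallest p in the interaction, the 5 largest each way between tissues, up to 4 members with the smallest p of each list described, and Cdkn1a, Lrp2 and Sstr2. Genes outside the rule are said to be chosen after their values were seen. The groups, tests, lists, naming rule and most alternative settings were fixed before the data were examined. An adipocyte marker covariate, and fits without control replicate 1, were added after the data had been seen.

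Same-numbered arrays of cortex and medulla were compared by the correlation of their deviations from the group means. The 3 control pairs had correlations between 0.614 and 0.659, so the replicate number pairs them, and the blocked value is given beside the comparison of tissues. Over all 18 pairs the correlations ran from -0.304 to 0.659, and 14 were above 0.1. The pairing comes from these values, as the labels do not state it. Comparisons that share controls were set beside 100 draws of unchanged groups that share simulated controls. These controls were drawn, like the groups, from the pooled residuals of the tissue's arrays with random signs.

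Alternatives were the deposited normalisation, no background correction (with a signal floor of 16), no detection filter, a stricter filter (detection p under 0.01 on every array of a group), every probe in place of 1 per gene, the replicate number as a block, a fit of all 36 arrays, a stricter call (adjusted p under 0.01 and 1.5-fold), activity ranks, and each array left out in turn. The procedure was tested on simulated data in which a known share of genes was shifted. At 140 MBq the fit called 19.1% of 1.5-fold, 44.6% of 2-fold and 93.1% of 4-fold changes in cortex, and 29.4%, 79.7% and 96.6% in medulla. For the interaction the shares were 7.14%, 20.5% and 80.7%. A simulated list was called with an adjusted p of 3.44e-18, and 0 of 39 other lists were called. The simulated genes varied independently, so this does not show how often lists of correlated genes are called in error. Slide positions are not given in the sources used here, so no slide was fitted.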

Results

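The arrays measured messenger RNA in kidneys of Balb/c mice 24 h after injection of 177Lu-octreotate, a somatostatin analogue labelled with a beta-emitting isotope of lutetium. Peptides of this kind are used against neuroendocrine tumours and are filtered and taken up again by the renal proximal tubule. Injected activities were 1.3, 3.6, 14, 45 and 140 MBq, beside a group at 0 MBq that served as the control. Cortex and medulla were each hybridised to 3 bead arrays per activity, which gave 12 groups and 36 arrays. The median signal of an array lay between 112 and 225, and between 12152 and 13319 of the 25697 probes were detected (47.3 to 51.8%). The lowest median signals, 112 in cortex and 123 in medulla, belonged to control replicate 1 of each tissue. Changes are given as log2 differences ± SE against the 3 control arrays of the same tissue, with limma's adjusted p, and the number of arrays per group limits their precision. Nothing in the labels states that the 3 arrays of a group came from separate animals, so the p-values measure only the spread between these samples.

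The comparison of 140 MBq with 0 MBq asks how kidney tissue responded to the highest activity. In cortex the genes that rose most were targets of p53, the transcription factor that responds to DNA damage. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 3.65 ± 0.35 (12.5-fold, adjusted p = 4.25e-05), from a log2 signal of 8.22 ± 0.76 (SD, 3 arrays) in the controls to 11.86 ± 0.37. Phlda3, an inhibitor of Akt signalling, rose by 3.67 ± 0.66 (12.7-fold, adjusted p = 0.0116), and the epoxide hydrolase Ephx1 by 2.91 ± 0.23 (7.51-fold, adjusted p = 8.86e-06). Gtse1, detected on 1 of 3 control arrays, rose by 2.95 ± 0.29, the stress-responsive kinase Plk2 by 2.64 ± 0.28 and the cyclin gene Ccng1 by 2.05 ± 0.14 (adjusted p = 1.51e-06). Of 29 measured p53 targets 15 rose and 0 fell over all genes tested, 19 rose when adjusted over the list alone, and the median change was 0.95 (camera, adjusted p = 1.99e-28, and adjusted p = 7.23e-05 with an estimated correlation). The remaining largest rises were Cox6b2 (2.78 ± 0.32), the leukotriene synthase Ltc4s (2.69 ± 0.33), the carboxylesterase Ces2e (2.69 ± 0.28), the glutathione transferase Gsta1 (2.72 ± 0.58) and the DNA repair enzyme Mgmt (2.23 ± 0.28). Gsta1 was detected on 1 of 3 control arrays, and Ces2e and Mgmt on 2 of 3. Calls at 140 MBq ended without control replicate 1 for Gsta1 (2.47, adjusted p = 0.151), and without another array for Phlda3 (3.41, adjusted p = 0.0783 without 140 MBq replicate 3). Some of these calls also ended without control replicates 2 or 3 or 140 MBq replicates 1 or 3.

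**Figure D1:**
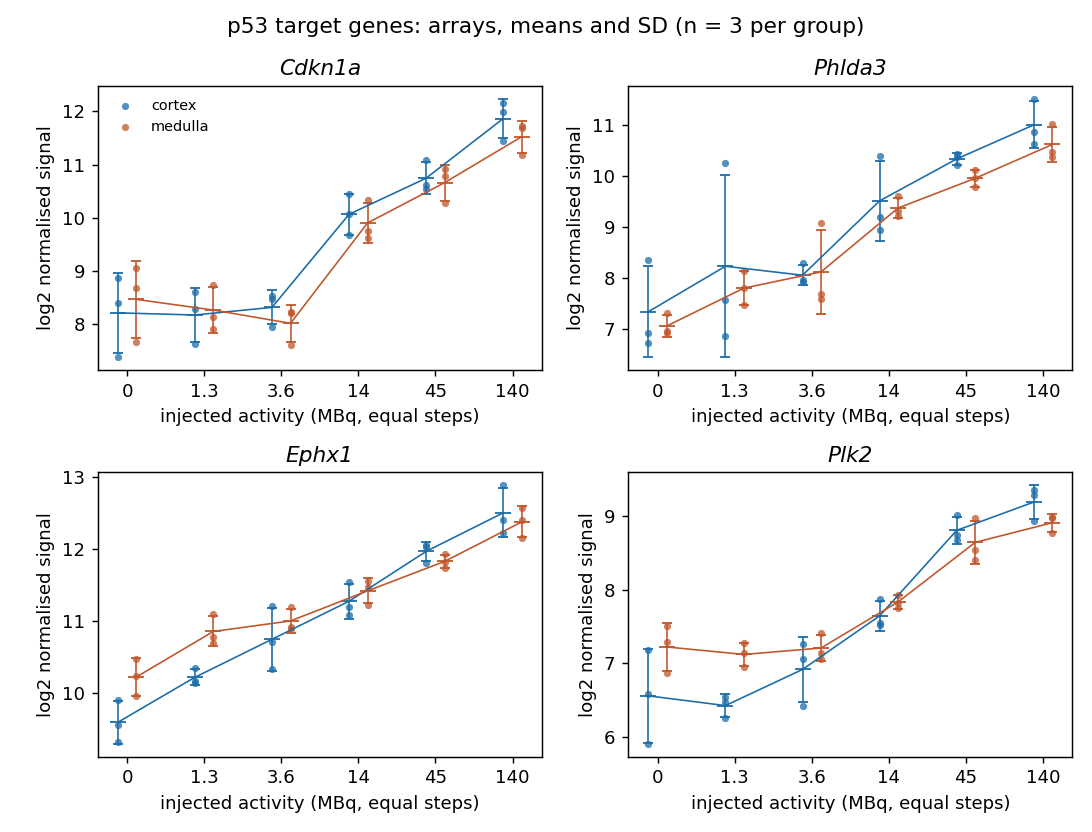
Log2 normalised signal of Cdkn1a, Phlda3, Ephx1 and Plk2 on each array (points) with the mean ± SD of 3 arrays (bars) against injected activity in MBq, drawn in equal steps, for cortex (blue) and medulla (orange). Cdkn1a rose from 8.22 ± 0.76 at 0 MBq to 11.86 ± 0.37 at 140 MBq in cortex and from 8.47 ± 0.72 to 11.52 ± 0.30 in medulla.

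Other genes also differed in cortex at 140 MBq. Circadian clock genes moved both ways: of 15 measured, 5 rose, among them Per2 (1.20 ± 0.16), Ciart (2.09 ± 0.33) and Per1 (1.65 ± 0.27), and 1 fell, and adjusted over the list alone 9 rose and 3 fell. Arntl, which encodes the clock activator BMAL1, was at least 3.22-fold lower (adjusted p = 0.00561). The list's median change was 0.84 (camera, adjusted p = 6.37e-05, and adjusted p = 0.0191 with an estimated correlation). Of 16 cholesterol synthesis genes 1 fell, the farnesyl diphosphate synthase Fdps (-1.15 ± 0.20), and 5 fell when adjusted over the list alone (camera, adjusted p = 2.85e-05, and adjusted p = 0.0269 with an estimated correlation). Of 21 oxidative stress genes under NRF2, 2 rose, Ephx1 and Gsta1, and 5 rose when adjusted over the list alone (camera, adjusted p = 2.85e-05, and adjusted p = 0.0191 with an estimated correlation). Of 13 glucocorticoid-responsive genes 3 rose, Ddit4 (1.61 ± 0.21), Per1 and Sgk1 (1.07 ± 0.22), and 4 when adjusted over the list alone (camera, adjusted p = 8.02e-05, and adjusted p = 0.145 with an estimated correlation). Camera called this list in 9 comparisons with 0 MBq, also without control replicate 1. Gpnmb, a kidney injury marker chosen after its values were seen and undetected in the controls, was at least 2.13-fold higher (adjusted p = 0.0473). Among the largest falls were the transferrin receptor Tfrc (-1.59 ± 0.33), the vasopressin receptor Avpr1a (-1.91 ± 0.27), the integrin Itgb6 (-1.26 ± 0.28) and Zbtb7a (-1.04 ± 0.18). Rnase6 and Ctsw were at least 2.14-fold and 1.73-fold lower. Of these falls, calls ended without control replicate 1 for Tfrc (-1.46), Itgb6 (-1.35), Zbtb7a (-0.97) and Ctsw (with adjusted p from 0.0539 to 0.133), and without another array for Fdps (-1.02, adjusted p = 0.0510 without 140 MBq replicate 2) and Rnase6 (adjusted p = 0.115 without 140 MBq replicate 3). Leaving out any array at 0 or 140 MBq ended at least 1 of these calls.

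Immune gene lists had medians below 0 in cortex at 140 MBq, against controls that differed among themselves. Ciita, the activator of MHC class II transcription, fell by 2.82 ± 0.63 (adjusted p = 0.0475) and was detected on 2 of 3 treated arrays. The call ended without control replicate 1 for Ciita (-2.26, adjusted p = 0.217). It also ended without control replicate 2 or 140 MBq replicates 1, 2 or 3. Ciita was the 1 of 18 MHC genes that fell, and also the 1 that fell when adjusted over the list alone (median -0.83; camera, adjusted p = 8.41e-05, and adjusted p = 0.570 with an estimated correlation). Of 17 myeloid markers 0 fell over all genes and 3 when adjusted over the list alone (median -0.46; camera, adjusted p = 6.37e-05, and adjusted p = 0.539 with an estimated correlation). No interferon-stimulated gene of 27 was called either way (median -0.50; camera, adjusted p = 0.00148, and adjusted p = 0.628 with an estimated correlation). On cortex control replicate 1 the means of the interferon, MHC and myeloid lists lay 1.87, 2.06 and 1.45 above their means over the 36 arrays, and on replicate 2 they lay 0.63, 1.00 and 0.74 above. On control replicate 3 they were at -0.20, -0.29 and -0.20, below all 3 arrays at 140 MBq for the interferon and MHC lists and among them for the myeloid list. Without control replicate 1 the medians were -0.07, -0.20 and -0.24, and the 3 list calls ended (camera, adjusted p = 0.959, 0.417 and 0.0749). Proximal tubule markers, 25 measured, had a median of 0.49 with 0 genes called (camera, adjusted p = 0.000780, and adjusted p = 0.539 with an estimated correlation), and on the same control array their mean lay at -1.14. Without it this call ended too (adjusted p = 0.914). Lrp2, which encodes the uptake receptor megalin, had a value of -0.10 ± 0.30 (adjusted p = 0.936). Its signal was weak, with group means from 5.87 to 6.26 in cortex and detection on 1 of 3 arrays at 14 MBq and 2 of 3 at 1.3, 3.6 and 45 MBq, so its values here and below do not exclude a change. Sstr2, the main receptor of the peptide, was detected on 0 arrays of either tissue. In all 105 of 10790 genes were called, 83 upward and 22 downward. The number was 59 and 54 without control replicates 1 and 2, and 56 and 49 without 140 MBq replicates 2 and 3. Without control replicate 3 it was 83 up and 66 down.

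At 45 MBq p53 targets also rose in cortex. Cdkn1a rose by 2.53 ± 0.35, adjusted p = 0.00239, Ephx1 by 2.37 ± 0.23, adjusted p = 9.84e-05, Phlda3 by 3.00 ± 0.66, adjusted p = 0.0420, and Ccng1 and Plk2 by 2.06 ± 0.14 and 2.25 ± 0.28. Of the 29 targets 9 rose, 16 when adjusted over the list alone (camera, adjusted p = 3.13e-15, and adjusted p = 0.00164 with an estimated correlation). Some lipid and clock genes rose beside them. Angptl4, an inhibitor of lipoprotein lipase that fatty acids induce, rose by 2.46 ± 0.35, Noct, a clock-controlled deadenylase, by 2.33 ± 0.51 and the nuclear receptor gene Ppara by 1.89 ± 0.32. Of 16 fatty acid oxidation and PPARA genes 3 rose, 5 when adjusted over the list alone (camera, adjusted p = 1.00e-06, and adjusted p = 0.133 with an estimated correlation), and of 15 clock genes 5 rose and 1 fell, 9 and 3 when adjusted over the list alone (camera, adjusted p = 0.000134, and adjusted p = 0.0538 with an estimated correlation). Here calls ended without control replicate 1 for Noct (2.68, adjusted p = 0.0519), and without another array for Phlda3 (2.70, adjusted p = 0.166 without control replicate 2). Some of these calls also ended without control replicates 2 or 3 or 45 MBq replicates 1, 2 or 3. The adipocyte marker list lay 1.31 and 2.35 above its mean over the 36 arrays on cortex 45 MBq replicates 1 and 3.

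Immune genes were among the falls in cortex at 45 MBq. Ciita was at least 6.28-fold lower (adjusted p = 0.0272). The interferon-induced GTPase Ifi47 fell (-2.81 ± 0.61), as did the macrophage marker Adgre1 (-2.57 ± 0.54, detected on 2 of 3 treated arrays), and the lymphocyte antigen gene Ly86 (-2.43 ± 0.49) and the chemokine Ccl12 (-2.35 ± 0.40), detected on 1 of 3 each. Of 18 MHC genes 2 fell, Ciita and Tapbp (-1.06 ± 0.23), and 15 when adjusted over the list alone (camera, adjusted p = 1.47e-12, and adjusted p = 0.211 with an estimated correlation). Of 17 myeloid markers 2 fell, and 14 when adjusted over the list alone (camera, adjusted p = 6.12e-12, and adjusted p = 0.135 with an estimated correlation). Of 27 interferon-stimulated genes 0 fell over all genes and 9 when adjusted over the list alone (camera, adjusted p = 5.12e-10, and adjusted p = 0.249 with an estimated correlation). Control replicate 1 held the highest level of each of these lists among the cortex arrays, as given above. Without it the medians moved from -1.02 to -0.35 for interferon, from -1.51 to -0.86 for MHC and from -1.58 to -1.01 for myeloid genes, each still called. Lrp2 had a value of 0.10 ± 0.30. The 107 called genes, 65 up and 42 down, became 50, 40 and 349 without control replicates 1, 2 and 3, and 31, 21 and 56 without 45 MBq replicates 1, 2 and 3. The balance turned without control replicate 3, to 130 up and 219 down. The named calls ended without control replicate 1 for Ciita, Ifi47 (-1.95), Adgre1 (-2.19) and Ly86 (-1.94) (with adjusted p from 0.139 to 0.178), and without another array for Ccl12 (-2.18, adjusted p = 0.0657 without 45 MBq replicate 2). Leaving out control replicate 2 or 45 MBq replicates 1, 2 or 3 also ended at least 1 of these calls.

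At 14 MBq myeloid and endothelial genes were among the falls in cortex. The neutrophil calprotectin gene S100a8 was at least 8.34-fold lower (adjusted p = 0.0198), and its partner S100a9 (-2.75 ± 0.58), Ciita (-2.78 ± 0.63), the oxysterol enzyme Ch25h (-2.66 ± 0.53) and Ly86 (-2.56 ± 0.49) fell. These last 4 were each detected on 1 of 3 treated arrays. These 5 calls ended without control replicate 1 for S100a8, Ciita (-2.23), S100a9 (-2.37), Ch25h (-2.44) and Ly86 (-2.07) (with adjusted p from 0.0920 to 0.187). At least 1 of these calls also ended without control replicate 2 or 14 MBq replicates 1, 2 or 3. Of 17 myeloid markers 3 fell, 14 when adjusted over the list alone (camera, adjusted p = 1.26e-09, and adjusted p = 0.187 with an estimated correlation). Of 16 endothelial markers 2 fell, Egfl7 (-1.31 ± 0.29) and Plvap (-1.37 ± 0.30), and 13 when adjusted over the list alone (median -1.15; camera, adjusted p = 2.39e-11, and adjusted p = 0.117 with an estimated correlation). Of 7 podocyte markers 1 fell, the phosphatase Ptpro (-2.24 ± 0.51, detected on 1 of 3 treated arrays), and 4 when adjusted over the list alone (camera, adjusted p = 0.000102, and adjusted p = 0.101 with an estimated correlation). Replicate 3 lay apart: the endothelial and podocyte means were at -0.20 and -0.07 on it, at -1.49 and -1.48 on replicate 1 and at -1.13 and -0.54 on replicate 2, against 0.44, 0.02 and -0.04 and 0.63, 0.36 and 0.34 on the controls. Of 18 MHC genes 1 fell, 8 when adjusted over the list alone (camera, adjusted p = 1.37e-07, and adjusted p = 0.277 with an estimated correlation), and of 27 interferon genes 0 and 10 (camera, adjusted p = 5.55e-08, and adjusted p = 0.277 with an estimated correlation). Without control replicate 1, where these lists were highest, the medians were -0.49 for interferon, -0.73 for MHC and -0.89 for myeloid genes, against -1.04, -1.39 and -1.31 with it.

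Among the rises in cortex at 14 MBq, Cyp24a1, the enzyme that degrades active vitamin D, rose by 3.26 ± 0.68 (9.55-fold, adjusted p = 0.0305), and Pck1, the rate-limiting enzyme of gluconeogenesis, by 3.10 ± 0.69 (8.58-fold, adjusted p = 0.0396). Angptl4 rose by 2.70 ± 0.35, the mitochondrial carrier Slc25a25 by 2.33 ± 0.37 and Ciart by 2.28 ± 0.33. The control signal of Cyp24a1 ranged from 7.57 to 10.95 and that of Pck1 from 7.52 to 9.80, lowest on control replicate 1. In these rises calls ended without control replicate 1 for Cyp24a1 (2.22) and Pck1 (2.41) (with adjusted p from 0.0792 to 0.182), and without another array for Slc25a25 (2.02, adjusted p = 0.0519 without 14 MBq replicate 1). Some of these calls also ended without control replicate 2 or 14 MBq replicates 1, 2 or 3. With the replicate number as a block neither Cyp24a1 nor Pck1 was called (adjusted p = 0.0579 and 0.0698). Of 16 fatty acid oxidation and PPARA genes 3 rose, with Slc25a20 (1.41 ± 0.26) and Ppara (1.43 ± 0.32) beside Angptl4, and 6 when adjusted over the list alone (camera, adjusted p = 1.50e-08, and adjusted p = 0.0748 with an estimated correlation). Of 29 p53 targets 5 rose, among them Ephx1 (1.68 ± 0.23), Cdkn1a (1.85 ± 0.35), Ccng1 (1.23 ± 0.14) and Zmat3 (1.23 ± 0.25), and 10 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 5.55e-08, and adjusted p = 0.0360 with an estimated correlation). Lrp2 had a value of -0.23 ± 0.30. The adipocyte and adrenal marker lists lay 2.99 and 5.54 above their means over the 36 arrays on cortex 14 MBq replicate 3. Of 148 called genes 58 rose and 90 fell. There were 28, 30 and 345 (95 up and 250 down) without control replicates 1, 2 and 3, and 24, 33 and 348 without 14 MBq replicates 1, 2 and 3. The balance was 16 up and 12 down and 18 up and 12 down without control replicates 1 and 2, and 12 up and 12 down and 19 up and 14 down without 14 MBq replicates 1 and 2.

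At 3.6 and 1.3 MBq the clock gene Arntl lay lower and the lipase inhibitor gene Angptl4 higher in cortex. Arntl was at least 3.02-fold lower at 3.6 MBq (adjusted p = 0.00521) and fell by 1.91 ± 0.37 at 1.3 MBq (adjusted p = 0.0393), where it was detected on 1 of 3 arrays. Angptl4 rose by 2.34 ± 0.35 and 2.62 ± 0.35, and Slc25a25 by 2.35 ± 0.37 and 2.17 ± 0.37. At 3.6 MBq Ciart rose by 2.05 ± 0.33, the progestin receptor Paqr7 by 1.86 ± 0.35 and the coenzyme A carrier Slc25a42 by 1.78 ± 0.23. At 1.3 MBq the serine synthesis enzyme Psat1 rose by 2.48 ± 0.44, the lipolysis inhibitor G0s2 by 2.25 ± 0.38, and the transcription factor Creb3l3 was at least 3.18-fold higher. Fatty acid oxidation and PPARA genes numbered 2 and 3 risen of 16 at 3.6 and 1.3 MBq, 6 and 13 when adjusted over the list alone. Their camera adjusted p was 1.77e-06 at 3.6 MBq (adjusted p = 0.201 with an estimated correlation) and 1.06e-14 at 1.3 MBq (adjusted p = 0.0288 with an estimated correlation). The adipocyte marker list lay 2.74 above its mean over the 36 arrays on cortex 1.3 MBq replicate 2, and its member Ucp1, chosen after its values were seen, had a mean log2 signal of 9.57 ± 4.26 (SD) at 1.3 MBq against 5.39 ± 0.53 in the controls (adjusted p = 0.322). Of 7 liver markers 0 were called at 1.3 MBq and 3 rose when adjusted over the list alone (median 0.79; camera, adjusted p = 0.00161, and adjusted p = 0.0530 with an estimated correlation), and their mean lay at 0.63, 1.20 and 0.27 on the 3 arrays against -0.64, -0.43 and -0.23 on the controls. At 3.6 MBq calls ended without control replicate 1 for Slc25a25 (2.26), Ciart (1.87) and Paqr7 (1.33) (with adjusted p from 0.0512 to 0.0659). Leaving out 3.6 MBq replicates 2 or 3 also ended at least 1 of these calls. At 1.3 MBq they ended without control replicate 1 for Psat1 (2.23), G0s2 (2.12), Creb3l3, Slc25a25 (2.07) and Arntl (-1.38) (with adjusted p from 0.103 to 0.123). At least 1 of these calls also ended without control replicate 2 or 1.3 MBq replicates 1, 2 or 3. Clock genes numbered 6 risen and 1 fallen at 3.6 MBq (camera, adjusted p = 0.000106, and adjusted p = 0.0949 with an estimated correlation), and 1 risen, Per2 (0.97 ± 0.16), and 1 fallen at 1.3 MBq (camera, adjusted p = 0.0187, and adjusted p = 0.303 with an estimated correlation). Adjusted over the list alone, 9 rose and 3 fell at 3.6 MBq, and 7 rose and 2 fell at 1.3 MBq. The clock call at 1.3 MBq ended without control replicate 1 (adjusted p = 0.112).

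The remaining named falls at 3.6 MBq were Ccl12 (-1.94 ± 0.40), the peptide transporter Slc15a3 (-1.89 ± 0.32, detected on 1 of 3 arrays), Nsd1 (-1.75 ± 0.16) and Pdgfb (-1.24 ± 0.22), and at 1.3 MBq Nsd1 (-1.60 ± 0.16), Wdfy3 (-1.37 ± 0.19), Cntln (-1.36 ± 0.19, detected on 2 of 3 arrays) and Zbtb7a (-1.15 ± 0.18). Nsd1, a histone methyltransferase gene, was measured by a second probe whose change was 0.25 at 3.6 MBq, so its fall rests on 1 probe. The 3.6 MBq calls ended without control replicate 1 for Ccl12 (-1.84), Slc15a3 (-1.59) and Pdgfb (-1.32) (with adjusted p from 0.0512 to 0.166). Some of these calls also ended without control replicate 2 or 3.6 MBq replicates 2 or 3. The 1.3 MBq call ended without control replicate 1 for Zbtb7a (-1.08, adjusted p = 0.0753). It also ended without 1.3 MBq replicates 2 or 3. Of the 29 p53 targets 2 rose at 3.6 MBq, Ccng1 (0.95 ± 0.14) and Ephx1 (1.15 ± 0.23), also 2 when adjusted over the list alone (camera, adjusted p = 0.0270, and adjusted p = 0.276 with an estimated correlation), and 0 rose at 1.3 MBq. Cdkn1a had values of 0.10 ± 0.35 and -0.04 ± 0.35 at 3.6 and 1.3 MBq, and Lrp2 of -0.20 ± 0.30 and -0.28 ± 0.30. Interferon-stimulated genes had 0 called at both activities and medians of -0.96 and -0.92, with 6 and 2 lower when adjusted over the list alone. Their camera adjusted p was 4.45e-11 at 3.6 MBq (adjusted p = 0.276 with an estimated correlation) and 3.73e-08 at 1.3 MBq (adjusted p = 0.486 with an estimated correlation). The medians were -0.48 and -0.44 without control replicate 1. At 3.6 MBq 47 genes were called, 33 up and 14 down, and at 1.3 MBq 36, of which 22 rose and 14 fell. The 47 became 17, 30 and 242 without control replicates 1, 2 and 3, and 431, 19 and 13 without 3.6 MBq replicates 1, 2 and 3. Their balance turned to 96 up and 146 down without control replicate 3, and to 128 up and 303 down without 3.6 MBq replicate 1. The 36 became 12, 18 and 157 without the same controls, and 10, 14 and 18 without 1.3 MBq replicates 1, 2 and 3, with 77 up and 80 down without control replicate 3 and 5 each way without 1.3 MBq replicate 1.

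The trend asks which genes rose or fell with activity among the 15 treated cortex arrays, without the controls. Each doubling of activity raised Cdkn1a by 0.58 ± 0.04, adjusted p = 1.57e-06, Plk2 by 0.43 ± 0.03, adjusted p = 8.93e-07, Ephx1 by 0.34 ± 0.03 and Ccng1 by 0.25 ± 0.02. Gtse1 rose too: it was not detected at 1.3 MBq and was at least 6.18-fold higher at 140 MBq. Of 29 p53 targets 14 rose, 20 when adjusted over the list alone (camera, adjusted p = 4.43e-36, and adjusted p = 1.48e-05 with an estimated correlation). Oxidative stress genes rose for 2 of 21, Ephx1, which is also on the p53 list, and Gsta3 (0.10 ± 0.02), 3 when adjusted over the list alone (camera, adjusted p = 0.000281, and adjusted p = 0.0114 with an estimated correlation). The genes that fell with the smallest p were Grpel2 (-0.14 ± 0.02), Serpinf2 (-0.22 ± 0.04), Metrnl (-0.15 ± 0.02), Ctsw (at least 1.37-fold lower at 140 than at 1.3 MBq) and Mrpl51 (-0.13 ± 0.02). Metrnl and Mrpl51 were detected on 2 of 3 arrays at 140 MBq. The calls of Ctsw and Mrpl51 ended without 140 MBq replicate 2 (adjusted p = 0.0531 and 0.0713), and that of Mrpl51 also without 1.3 MBq replicates 2 and 3. Of 18 MHC genes 0 were called either way, also over the list alone, with a median slope of -0.0643 (camera, adjusted p = 0.0136, and adjusted p = 0.741 with an estimated correlation). Fatty acid oxidation and PPARA genes had 0 called and 5 lower when adjusted over the list alone (camera, adjusted p = 1.33e-05, and adjusted p = 0.122 with an estimated correlation), and cholesterol genes 0 and 2 (camera, adjusted p = 5.12e-05, and adjusted p = 0.0540 with an estimated correlation). In all 78 of 10565 genes changed with activity, 67 upward and 11 downward, and 45 without 140 MBq replicate 2. The test of any difference among the 6 groups, controls included, called 78 of 10790 genes. That number was 47 and 125 without control replicates 2 and 3, 353 without 3.6 MBq replicate 1 and 192 without 14 MBq replicate 3.

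In medulla at 140 MBq p53 targets again led the rises. Phlda3 rose by 3.56 ± 0.31 (11.8-fold, adjusted p = 1.54e-05), Cdkn1a by 3.05 ± 0.33 (8.31-fold, adjusted p = 0.000123) and Ephx1 by 2.15 ± 0.16, adjusted p = 6.83e-06. Gtse1 rose by 2.44 ± 0.29, the p53 antagonist Mdm2 by 1.45 ± 0.13 and Plk2 by 1.69 ± 0.18. Of 27 measured p53 targets 13 rose and 0 fell, and 17 rose when adjusted over the list alone (median 0.69; camera, adjusted p = 4.02e-24, and adjusted p = 7.75e-06 with an estimated correlation). Gsta1 (2.82 ± 0.49), Ltc4s (2.52 ± 0.22), Cox6b2 (2.30 ± 0.33), Ciart (2.26 ± 0.21) and Mgmt (2.05 ± 0.23) completed the largest rises with Ces2e, which was at least 4.41-fold higher. Gsta1, Gtse1 and Mgmt were detected on 1 of 3 control arrays each, and Ciart on 2 of 3. Of 21 oxidative stress genes 2 rose, 4 when adjusted over the list alone (camera, adjusted p = 0.000180, and adjusted p = 0.221 with an estimated correlation), and this call ended without control replicate 1 (adjusted p = 0.0747). Gpnmb was at least 2.54-fold higher (adjusted p = 0.00662).

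Clock, sterol and immune genes also differed in medulla at 140 MBq. Of 15 clock genes 8 rose, with Per1 (1.53 ± 0.21), Per2 (1.16 ± 0.19) and Usp2 (0.94 ± 0.14) beside Ciart, and 1 fell, Arntl, at least 3.45-fold lower (adjusted p = 0.000494). Adjusted over the list alone 9 rose and 3 fell (camera, adjusted p = 0.000183, and adjusted p = 0.0608 with an estimated correlation). Of 16 cholesterol synthesis genes 3 fell, the regulator Srebf2 (-0.76 ± 0.16), the squalene epoxidase Sqle (-0.72 ± 0.16) and Fdps (-0.64 ± 0.14), and 5 when adjusted over the list alone (camera, adjusted p = 2.03e-05, and adjusted p = 0.0348 with an estimated correlation). Of 15 fatty acid oxidation and PPARA genes 1 rose, Ppara (1.60 ± 0.25), and 4 when adjusted over the list alone (camera, adjusted p = 0.00204, and adjusted p = 0.595 with an estimated correlation). S100a8 fell (-2.51 ± 0.59) and was the 1 of 16 myeloid markers called, with 2 lower when adjusted over the list alone (camera, adjusted p = 0.000183, and adjusted p = 0.578 with an estimated correlation). Ciita fell (-2.39 ± 0.55, detected on 2 of 3 treated arrays) and was the 1 of 18 MHC genes called, also over the list alone (camera, adjusted p = 7.84e-06, and adjusted p = 0.578 with an estimated correlation), while no interferon-stimulated gene was called (camera, adjusted p = 0.00104, and adjusted p = 0.674 with an estimated correlation). Both gene calls ended without control replicate 1 for S100a8 (-2.12) and Ciita (-1.68) (with adjusted p from 0.155 to 0.181). At least 1 of these calls also ended without control replicate 2 or 140 MBq replicates 1, 2 or 3. On medulla control replicate 1 the interferon, MHC and myeloid means lay at 1.85, 2.07 and 1.87. Without that array their medians moved from -0.41, -0.91 and -0.51 to 0.03 (-0.01 in another fit), -0.19 and -0.14, and the calls ended (adjusted p = 0.776, 0.0995 and 0.165).

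Further falls in medulla at 140 MBq were Tfrc (-1.87 ± 0.26), Avpr1a (-1.72 ± 0.23), Wdfy3 (-1.61 ± 0.23), Sla (-1.52 ± 0.33), the clotting factor gene F8 (-1.44 ± 0.26, detected on 1 of 3 treated arrays), Glipr2 (-1.38 ± 0.24) and Nsd1 (-1.37 ± 0.16). Of these, calls ended without control replicate 1 for Sla (-1.15, adjusted p = 0.132), and without another array for F8 (-1.36, adjusted p = 0.0511 without 140 MBq replicate 1). Some of these calls also ended without control replicate 2 or 140 MBq replicates 1, 2 or 3. Other probes of Wdfy3, Sla and Nsd1 changed by 0.04, 0.23 and 0.33, so these falls rest on 1 probe each. Proximal tubule markers had 0 of 25 called and a median of 0.32 (camera, adjusted p = 0.0172, and adjusted p = 0.674 with an estimated correlation), and their mean on control replicate 1 lay at -1.37. Without it the median was 0.04, the direction of camera's test turned and the call ended (adjusted p = 0.584). Lrp2, detected on all medulla arrays with group means from 5.95 to 7.06, had a value of -0.31 ± 0.29 (adjusted p = 0.679). In all 165 of 10864 genes were called, 115 up and 50 down. The number was 101 and 296 without control replicates 1 and 3, the latter 168 up and 128 down, and 74 and 82 without 140 MBq replicates 1 and 3.

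At 45 MBq p53 targets rose in medulla. Phlda3 rose by 2.90 ± 0.31, adjusted p = 0.000244, Cdkn1a by 2.19 ± 0.33, adjusted p = 0.00216, and Ces2e was at least 3.87-fold higher. Of 27 p53 targets 9 rose, 15 when adjusted over the list alone (camera, adjusted p = 1.15e-13, and adjusted p = 0.000158 with an estimated correlation). Ciart rose by 2.42 ± 0.21 and Arntl was at least 3.34-fold lower. Of 15 clock genes 8 rose and 2 fell, 9 and 3 when adjusted over the list alone (camera, adjusted p = 9.95e-05, and adjusted p = 0.0860 with an estimated correlation). Angptl4 rose by 2.19 ± 0.38 and Ppara by 2.10 ± 0.25, which were 2 of the 3 fatty acid oxidation and PPARA genes of 15 that rose, and 7 rose when adjusted over the list alone (camera, adjusted p = 3.61e-06, and adjusted p = 0.25 with an estimated correlation). Of 25 proximal tubule markers 2 rose, Cyp4b1 (1.52 ± 0.33) and the organic anion transporter Slc22a6 (0.87 ± 0.18), and 9 when adjusted over the list alone (camera, adjusted p = 3.14e-07, and adjusted p = 0.258 with an estimated correlation). Without control replicate 1, where their mean lay at -1.37, the median moved from 0.66 to 0.28. Of 24 cell cycle genes 2 fell, Nusap1 (at least 1.92-fold lower) and Mcm6 (at least 1.66-fold lower), and adjusted over the list alone 1 rose and 10 fell (camera, adjusted p = 0.000103, and adjusted p = 0.25 with an estimated correlation). The list's mean lay at 0.36, 0.43 and -0.19 on the 3 controls and at -0.25, -0.31 and -0.27 on the arrays at 45 MBq, so control replicate 3 lay close to the treated arrays.

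Immune genes were again among the falls in medulla at 45 MBq. Ifi47 (-3.04 ± 0.60), Ciita (-2.54 ± 0.55, detected on 1 of 3 treated arrays), S100a8 (-2.46 ± 0.59) and Ly86 (-2.08 ± 0.46) fell. These 4 calls ended without control replicate 1 for Ifi47 (-2.16), Ciita (-1.83), S100a8 (-2.07) and Ly86 (-1.40) (with adjusted p from 0.0521 to 0.161). Leaving out control replicate 2 or 45 MBq replicates 1, 2 or 3 also ended at least 1 of these calls. Of 16 myeloid markers 3 fell, 16 when adjusted over the list alone (camera, adjusted p = 9.47e-12, and adjusted p = 0.231 with an estimated correlation), of 18 MHC genes 2 and 14 (camera, adjusted p = 5.46e-10, and adjusted p = 0.25 with an estimated correlation), of 27 interferon genes 2 and 10 (camera, adjusted p = 2.37e-09, and adjusted p = 0.336 with an estimated correlation), and of 14 inflammation genes 1, Il1b (-1.80 ± 0.32), and 8 (camera, adjusted p = 7.80e-07, and adjusted p = 0.25 with an estimated correlation). Without control replicate 1 the medians moved from -1.30 to -0.92 for myeloid, from -1.56 to -0.82 for MHC and from -0.80 to -0.40 for interferon genes. Lrp2 had a value of 0.79 ± 0.29 (adjusted p = 0.151). The 250 called genes, 153 up and 97 down, became 67, 95 and 817 without control replicates 1, 2 and 3, and 76 and 101 without 45 MBq replicates 1 and 3. The balance turned to 384 up and 433 down without control replicate 3.

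At 14 MBq in medulla 263 of 10864 genes rose and 211 fell. Pck1 rose by 3.85 ± 0.69 (14.4-fold, adjusted p = 0.00950), Cyp24a1 by 3.26 ± 0.67 (adjusted p = 0.0177), the calcium-binding S100g by 2.52 ± 0.55, Ciart by 2.45 ± 0.21 and the glutamine synthetase Glul by 2.41 ± 0.47. Calls at 14 MBq ended without control replicate 1 for Cyp24a1 (2.39), S100g (2.34) and Glul (2.25) (with adjusted p from 0.0629 to 0.0832). At least 1 of these calls also ended without control replicate 2 or 14 MBq replicates 1, 2 or 3. Of 13 vitamin D and calcium-phosphate genes 3 rose, Cyp24a1, S100g and the receptor gene Vdr (1.13 ± 0.24), and 4 when adjusted over the list alone (camera, adjusted p = 0.0194, and adjusted p = 0.228 with an estimated correlation). Of 25 proximal tubule markers 4 rose, Pck1, Acsm2 (2.28 ± 0.45), Slc22a6 (0.66 ± 0.18) and Hnf4a (0.50 ± 0.13), and 7 when adjusted over the list alone (camera, adjusted p = 4.20e-06, and adjusted p = 0.330 with an estimated correlation). The median of this list moved from 0.50 to 0.18 (adjusted p = 0.0231) without control replicate 1, where its mean lay at -1.37. Of 15 clock genes 8 rose and 2 fell, 9 and 4 when adjusted over the list alone (camera, adjusted p = 0.000204, and adjusted p = 0.110 with an estimated correlation). Of 27 p53 targets 5 rose, among them Phlda3 (2.32 ± 0.31), Ccng1 (1.20 ± 0.20), Zmat3 (1.01 ± 0.19) and Cdkn1a (1.43 ± 0.33), and 9 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 1.79e-06, and adjusted p = 0.00857 with an estimated correlation).

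Myeloid and MHC genes were among the falls in medulla at 14 MBq. S100a8 (-3.22 ± 0.59, detected on 2 of 3 treated arrays), S100a9 (-2.67 ± 0.54) and the interferon-inducible Gvin1 (-2.38 ± 0.43) fell, Ciita was at least 5.15-fold lower, and the protease Adamts4, undetected on the treated arrays, was also lower (adjusted p = 0.0419). In these falls calls ended without control replicate 1 for S100a8 (-2.83), S100a9 (-2.61), Ciita and Adamts4 (with adjusted p from 0.0542 to 0.0844), and without another array for Gvin1 (-2.16, adjusted p = 0.0550 without 14 MBq replicate 3). Some of these calls also ended without control replicate 2 or 14 MBq replicates 1, 2 or 3. Of 16 myeloid markers 8 fell, 14 when adjusted over the list alone (camera, adjusted p = 8.10e-10, and adjusted p = 0.248 with an estimated correlation), with C1qb at -1.68 ± 0.40. Of 18 MHC genes 3 fell, 11 when adjusted over the list alone (camera, adjusted p = 1.79e-06, and adjusted p = 0.365 with an estimated correlation), with H2-Eb1 at -2.01 ± 0.50. Of 27 interferon genes 4 fell, 12 when adjusted over the list alone (camera, adjusted p = 8.84e-07, and adjusted p = 0.385 with an estimated correlation), with Irf1 at -1.46 ± 0.37 and Stat2 at -1.19 ± 0.31. Without control replicate 1 these 3 medians moved from -1.32, -1.33 and -0.93 to -1.02, -0.66 and -0.40. Of 16 endothelial markers 1 fell, the transcription factor Ets1 (-0.96 ± 0.26), 2 when adjusted over the list alone (camera, adjusted p = 0.000204, and adjusted p = 0.330 with an estimated correlation). Lrp2 had a value of -0.22 ± 0.29. The adrenal marker list lay 4.74 above its mean over the 36 arrays on medulla 14 MBq replicate 3. The 474 calls became 94, 247 and 871 without control replicates 1, 2 and 3, and 109, 133 and 65 without 14 MBq replicates 1, 2 and 3. They turned to 389 up and 482 down without control replicate 3. Distal convoluted and connecting tubule markers lay at 0.0894, 0.235 and 0.163 on the 3 medulla arrays at 14 MBq, and at -0.0364 or below on the other 15.

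At 3.6 MBq the medulla raised Angptl4 (2.12 ± 0.38), the acyl-CoA thioesterase Acot2 (2.06 ± 0.41), Ciart (2.05 ± 0.21, adjusted p = 0.000275; detected on 2 of 3 controls), Paqr7 (1.82 ± 0.22) and G0s2 (1.75 ± 0.37). Arntl was at least 3.29-fold lower, and S100a8 (-2.78 ± 0.59), the cytokine signalling inhibitor Socs3 (-2.41 ± 0.57), S100a9 (-2.31 ± 0.54) and Serpinb6b (-1.71 ± 0.32) fell. Of 15 clock genes 8 rose and 1 fell, 9 and 2 when adjusted over the list alone (camera, adjusted p = 2.54e-05, and adjusted p = 0.0850 with an estimated correlation). Another probe of Acot2 had a change of 0.03, so its rise rests on 1 probe. Named calls ended without control replicate 1 for Acot2 (1.90), G0s2 (1.49), S100a8 (-2.39), Socs3 (-2.51), S100a9 (-2.25) and Serpinb6b (-1.50) (with adjusted p from 0.0642 to 0.114). Leaving out control replicate 2 or 3.6 MBq replicates 1, 2 or 3 also ended at least 1 of these calls. That of Angptl4 ended without control replicate 2, where it had a value of 1.93. Of 15 fatty acid oxidation and PPARA genes 4 rose, 6 when adjusted over the list alone (camera, adjusted p = 2.70e-06, and adjusted p = 0.371 with an estimated correlation), and the adipocyte marker list lay 1.22 above its mean over the 36 arrays on medulla 3.6 MBq replicate 2. Of 16 myeloid markers 2 fell, 12 when adjusted over the list alone (camera, adjusted p = 2.56e-09, and adjusted p = 0.371 with an estimated correlation), and the median moved from -1.08 to -0.63 without control replicate 1. Of 16 cholesterol genes 3 fell, Fdps (-0.68 ± 0.14), Srebf2 (-0.71 ± 0.16) and Sqle (-0.72 ± 0.16), and 5 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.0306, and adjusted p = 0.371 with an estimated correlation). Cdkn1a had a value of -0.45 ± 0.33 and Lrp2 of 0.26 ± 0.29. In all 207 genes were called, 143 up and 64 down. The number was 89, 86 and 711 (379 up and 332 down) without control replicates 1, 2 and 3, and 79, 52 and 340 without 3.6 MBq replicates 1, 2 and 3, the last with 155 up and 185 down.

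At 1.3 MBq the gene that rose most in medulla was Ucp1, the uncoupling protein of brown fat, at least 14.2-fold higher (adjusted p = 0.0420) and not detected in the controls. Its log2 signal was 9.47 ± 1.89 (SD), from 7.54 to 11.32. The call ended without 1.3 MBq replicates 1 and 2 (adjusted p = 0.203 and 0.105), without control replicates 1 and 2 (adjusted p = 0.154 and 0.102) and with the replicate number as a block (adjusted p = 0.0689). Ucp1 was the 1 of 11 adipocyte markers called, also over the list alone (camera, adjusted p = 0.0399, and adjusted p = 0.552 with an estimated correlation). Angptl4 rose by 2.38 ± 0.38, Bbox1, the last enzyme of carnitine synthesis, by 2.44 ± 0.46 (detected on 2 of 3 controls), Acot2 by 2.17 ± 0.41 and G0s2 by 1.95 ± 0.37. Another probe of Acot2 had a change of -0.15, so its rise rests on 1 probe. Of 15 fatty acid oxidation and PPARA genes 4 rose, with the carnitine carrier Slc25a20 (1.44 ± 0.25) and Cpt2 (0.92 ± 0.20) beside Angptl4 and Acot2, and 12 when adjusted over the list alone (camera, adjusted p = 6.67e-13, and adjusted p = 0.201 with an estimated correlation). Of 6 liver markers 0 were called and 3 rose when adjusted over the list alone (median 0.55; camera, adjusted p = 0.00515, and adjusted p = 0.201 with an estimated correlation), and their mean lay at 0.69, 0.74 and 0.52 on the 3 arrays against -0.01, -0.35 and -0.01 on the controls. Of 15 clock genes 3 rose, Per2 (1.00 ± 0.19), Ciart (0.97 ± 0.21) and Usp2 (0.67 ± 0.14), and Arntl fell by 1.53 ± 0.26 (adjusted p = 0.0144), and adjusted over the list alone 9 rose and 3 fell (camera, adjusted p = 0.00316, and adjusted p = 0.213 with an estimated correlation). The chemokine Cxcl10 (-1.72 ± 0.38), Glipr2 (-1.64 ± 0.24, detected on 2 of 3 treated arrays), Nsd1 (-1.56 ± 0.16) and Wdfy3 (-1.17 ± 0.23) fell. Calls other than that of Ucp1 ended without control replicate 1 for Bbox1 (1.85), Acot2 (2.00), G0s2 (1.69), Cxcl10 (-1.11) and Wdfy3 (-1.13) (with adjusted p from 0.0852 to 0.111), and without another array for Angptl4 (1.95, adjusted p = 0.0694 without 1.3 MBq replicate 1), Glipr2 (-1.53, adjusted p = 0.0659 without 1.3 MBq replicate 1) and Arntl (-1.55, adjusted p = 0.0694 without 1.3 MBq replicate 1). At least 1 of these calls also ended without control replicate 2 or 1.3 MBq replicates 1, 2 or 3. Other probes of Nsd1 and Wdfy3 had changes of -0.05 and -0.14. Of 27 p53 targets 0 rose and 1 fell, Sesn2 (-0.76 ± 0.16). Of 27 interferon genes 1 fell, Cxcl10, and 13 when adjusted over the list alone (camera, adjusted p = 2.36e-14, and adjusted p = 0.346 with an estimated correlation), with a median of -1.17 that was -0.51 without control replicate 1. Cdkn1a had a value of -0.20 ± 0.33 and Lrp2 of 0.06 ± 0.29. The 85 called genes, 64 up and 21 down, became 32, 43 and 425 (219 up and 206 down) without control replicates 1, 2 and 3, and 5, 52 and 26 without 1.3 MBq replicates 1, 2 and 3.

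Among the 15 treated medulla arrays each doubling of activity raised Cdkn1a by 0.54 ± 0.05, adjusted p = 9.16e-06, Plk2 by 0.29 ± 0.02, adjusted p = 6.82e-06, Phlda3 by 0.44 ± 0.04, Ltc4s by 0.33 ± 0.03 and Ephx1 by 0.23 ± 0.02. Of 27 p53 targets 12 rose, 19 when adjusted over the list alone (camera, adjusted p = 1.28e-30, and adjusted p = 2.58e-05 with an estimated correlation). Of 21 oxidative stress genes 2 rose, Ephx1, which is also on the p53 list, and Gsta3 (0.10 ± 0.02), 3 when adjusted over the list alone (camera, adjusted p = 0.000406, and adjusted p = 0.0365 with an estimated correlation). Of 26 interferon genes 3 rose, Isg15 (0.25 ± 0.03), Oasl1 (0.17 ± 0.03) and Ifitm3 (0.11 ± 0.02), 8 when adjusted over the list alone (camera, adjusted p = 1.96e-05, and adjusted p = 0.441 with an estimated correlation). Cholesterol genes fell for 1 of 16, Stard4 (-0.09 ± 0.02), 2 when adjusted over the list alone (camera, adjusted p = 0.000288, and adjusted p = 0.0331 with an estimated correlation), and fatty acid oxidation and PPARA genes had 0 called, with 1 higher and 7 lower when adjusted over the list alone (camera, adjusted p = 8.07e-05, and adjusted p = 0.394 with an estimated correlation). The genes that fell with the smallest p were Serpinf2 (-0.19 ± 0.02), Pdzrn3 (-0.12 ± 0.02), the sodium-phosphate transporter family gene Slc17a4 (at least 1.14-fold lower at 140 than at 1.3 MBq), Stard4 and Grpel2 (-0.12 ± 0.02). The calls of Stard4 and Grpel2 ended without 140 MBq replicates 2 and 1 (adjusted p = 0.0502 and 0.0580). Of 18 MHC genes 0 were called either way, with a median slope of -0.0369 (camera, adjusted p = 0.0847, and adjusted p = 0.685 with an estimated correlation). In all 88 of 10693 genes changed with activity, 64 up and 24 down, and the deposited normalisation split its 133 calls into 83 up and 50 down. The test of any difference among the 6 groups called 561 of 10864 genes. That number was 992 without control replicate 3, and it was 348 and 346 without 140 MBq replicates 1 and 3, 359 without 45 MBq replicate 1, 230, 238 and 230 without 14 MBq replicates 1, 2 and 3, and 289 and 266 without 3.6 MBq replicates 1 and 2.

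**Figure D2:**
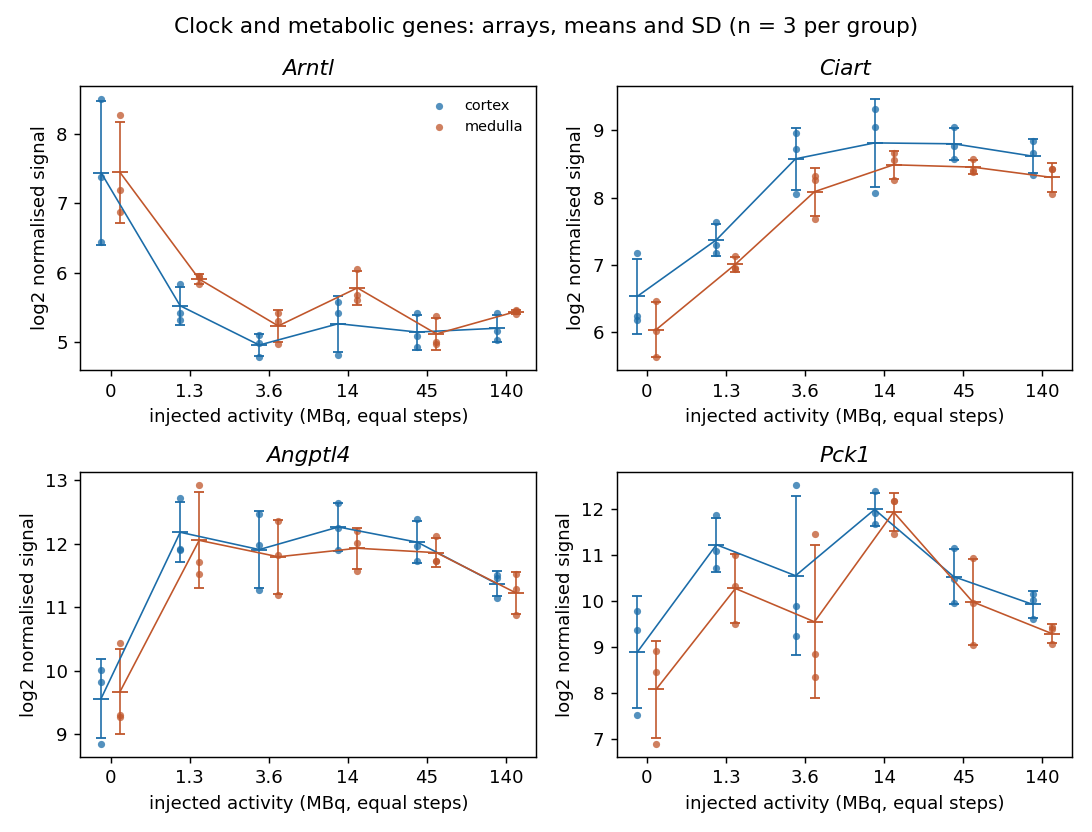
Log2 normalised signal of Arntl, Ciart, Angptl4 and Pck1 on each array (points) with the mean ± SD of 3 arrays (bars) against injected activity in MBq, drawn in equal steps, for cortex (blue) and medulla (orange). Arntl lay lower and Ciart and Angptl4 higher than in the controls at the activities given in the text, and Pck1 was highest at 14 MBq in both tissues.

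A further question is which genes differed from the controls at every activity. In cortex 13 genes were called at all 5 activities, 7 upward and 6 downward, among them Arntl, Per2, Angptl4, the coenzyme A carrier Slc25a42, the carboxylesterase Ces2g and Nsd1. Angptl4 in cortex lay between 1.81 ± 0.35 and 2.70 ± 0.35, and Per2 between 0.97 ± 0.16 and 1.58 ± 0.16. In medulla 21 were called at all 5, 13 upward and 8 downward, among them Arntl, Per2, Ciart, Usp2, Paqr7, Avpr1a and the AMP-activated kinase subunit gene Prkaa2 (0.69 ± 0.18 to 1.27 ± 0.18). Of 100 simulated sets of unchanged groups against shared controls 0 gave such a gene in either tissue. Pairs of activities shared 15 to 62 called genes of the same direction in cortex and 30 to 118 in medulla, with 0 opposite. Independent lists would share 0.0854 to 0.700 and 0.774 to 5.59, and simulated unchanged groups shared at most 31 and 18. The correlation of log2 changes across genes, which are not independent replicates, was 0.574 to 0.768 in cortex (simulated 0.423 to 0.524) and 0.369 to 0.754 in medulla (simulated 0.446 to 0.516). It lay above its simulated value in each pair but 3.6 and 14 MBq in medulla (0.369 against 0.486). Covariances were 0.0998 to 0.171 in cortex (simulated 0.0550 to 0.0629) and 0.0695 to 0.126 in medulla (simulated 0.0306 to 0.0371). With 3 controls per tissue these could not be divided into separate sets, so part of the excess may come from the shared controls.

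**Figure D3:**
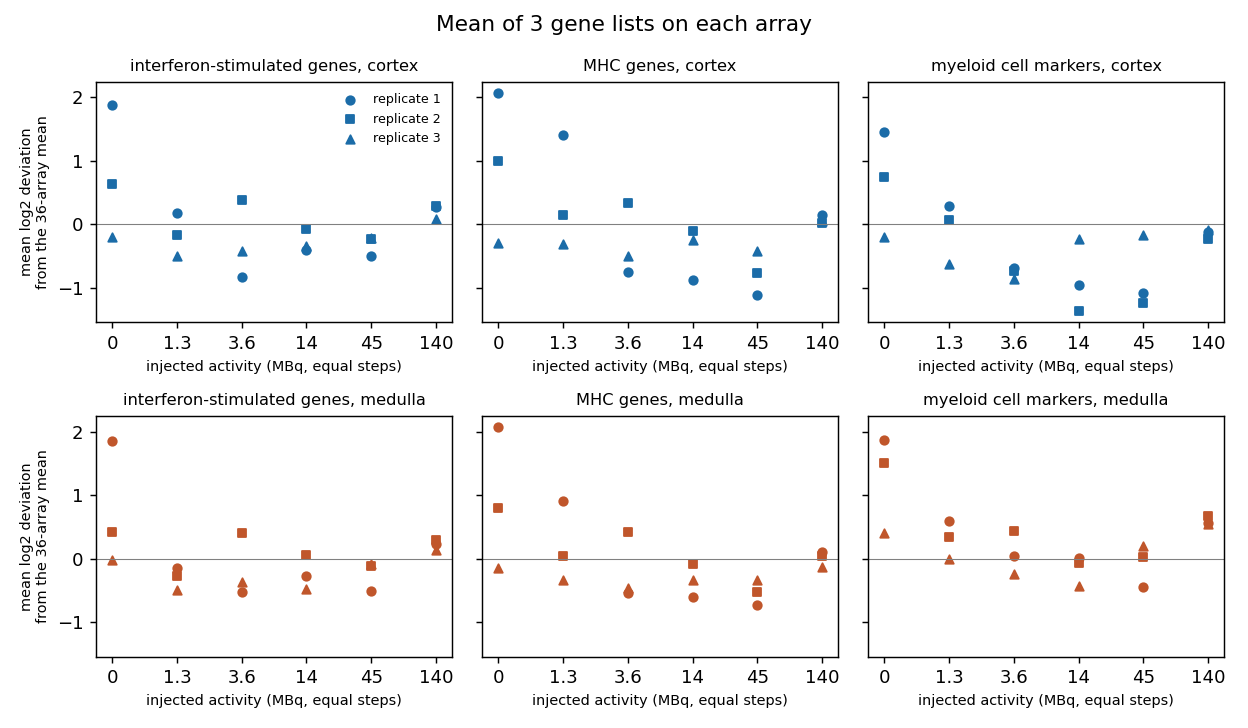
Mean log2 deviation from the 36-array mean of interferon-stimulated genes, MHC genes and myeloid markers on each array against injected activity in MBq, with cortex in the top panels, medulla in the bottom panels, and circles, squares and triangles for replicates 1, 2 and 3. Control replicate 1 lies at 1.87, 2.06 and 1.45 in cortex and at 1.85, 2.07 and 1.87 in medulla.

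The control groups of both tissues were compared to check the tissue labels. Genes of the inner kidney were higher in medulla: the urea transporter Slc14a2 (cortex minus medulla -5.46 ± 0.96, adjusted p = 0.00467), the peptide Npy (-4.05 ± 0.65), the betaine transporter Slc6a12 (-3.36 ± 0.77, adjusted p = 0.0447) and the protease Corin (-3.17 ± 0.42). Lypd2 was at least 6.24-fold higher in medulla. Slc14a2, Slc6a12 and Corin were each detected on 1 of 3 cortex arrays. Higher in cortex were Hykk (1.45 ± 0.30), the urate transporter Slc2a9 (1.42 ± 0.28, detected on 2 of 3 medulla arrays) and Miip (0.89 ± 0.19). Of 8 osmolyte and medullary tonicity genes 2 were lower in cortex, 3 when adjusted over the list alone (camera, adjusted p = 0.00106, and adjusted p = 0.306 with an estimated correlation). The comparison called 44 genes, 3 higher in cortex and 41 in medulla. With the replicate number as a block, which the control arrays bear out, it called 155, 51 and 104. Without cortex control replicates 2 and 3 it called 21 and 71, and without medulla control replicates 1 and 3 it called 22 and 29. The calls of Hykk, Slc2a9, Miip and Slc6a12 ended without medulla control replicate 1 (adjusted p = 0.105, 0.141, 0.226 and 0.287), and some of them also without medulla control replicates 2 and 3 or cortex control replicates 1, 2 and 3.

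The last question is whether the response differed between the tissues. In a single fit of the 36 arrays 0 of 11465 genes passed limma's test of the tissue by activity interaction, and 186 had an unadjusted p under 0.05. The smallest p-values belonged to Wdr95, G6pc2, Riiad1, Auh, Svop, Adamts15, Ttbk2, Rspo3, Slc37a3 and Tmem17, each with an adjusted p of 1.00. Endothelial markers differed as a list at 14 MBq, lower in cortex, though with cortex replicate 3 at -0.20 (camera, adjusted p = 2.71e-09, and adjusted p = 0.375 with an estimated correlation), and so did p53 targets at 140 MBq, higher in cortex (camera, adjusted p = 0.000819, and adjusted p = 0.111 with an estimated correlation). Genes called in both tissues moved the same way. At 140 MBq 56 rose and 12 fell in both, at 45 MBq 51 and 18, at 14 MBq 44 and 41, at 3.6 MBq 26 and 8, and at 1.3 MBq 15 and 7, with 0 in opposite directions. Independent lists would share 0.891 rises at 140 MBq and 0.134 at 1.3 MBq. The control arrays pair by number, so these comparisons are not independent, and part of the overlap may come from the controls. In the trends 43 genes rose and 4 fell in both tissues, where independent lists would share 0.399 and 0.0257. Nor are these lists independent: same-numbered treated arrays of both tissues correlated at 1.3, 14 and 140 MBq (r = 0.138 to 0.339 across genes).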

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

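The adipocyte marker covariate and the fits without control replicate 1 were chosen after the results had been seen, and the other settings below were fixed beforehand. Most counts of the comparisons with 0 MBq moved by more than 1.5 times when an array was left out. Many also moved under other settings. The counts that moved are given here, those of left-out arrays as ranges, and for each the cause was not tested. The median signal of an array was 112 to 225 and detection reached 47.3 to 51.8% of probes, which limits what can be said of weakly expressed genes.

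With the deposited normalisation 56 genes were called in cortex at 1.3 MBq and 73 at 3.6 MBq, and in medulla 313 at 3.6 MBq, 864 among the 6 groups and 133 in the trend, where the share that rose went from 72.7 to 62.4%. Without background correction the counts were 55 and 76 in cortex at 1.3 and 3.6 MBq, and 317 and 864 in medulla at 3.6 MBq and among the groups, with 62.1% of the trend rising. Without a detection filter 90 genes were called in cortex at 14 MBq. The strict detection filter gave 60 and 80 in cortex at 1.3 and 3.6 MBq and 131 in medulla at 1.3 MBq. With every probe 67 were called between the tissues.

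With the replicate number as a block, cortex had 18, 82 and 68 calls at 1.3, 14 and 45 MBq, the medulla groups 352, and the comparison of tissues 155. The block changed no other count by more than 1.5 times. Of 18 same-numbered cortex and medulla pairs 14 correlated best with their own number, a hint only. At 3.6 MBq pairs 1 and 3 did not (r = -0.0713 and -0.304), nor did pairs 1 and 2 at 45 MBq. The blocked interaction, at 0, is thus a weak check. Within a tissue same-numbered arrays had mean correlations of -0.0620 in cortex and -0.0192 in medulla (other numbers 0.0311 and 0.00956). This gives no basis for a block. A fit of all 36 arrays called 227, 261, 523, 305 and 282 genes in cortex at 1.3, 3.6, 14, 45 and 140 MBq, and 56, 114, 168 and 161 in medulla at 1.3, 3.6, 14 and 45 MBq. An adjusted p under 0.01 with at least 1.5-fold change left 10, 13, 17, 22 and 40 in cortex and 9, 46, 51, 53 and 57 in medulla, by the construction of a stricter limit, and turned the balance in cortex at 14 MBq to 12 up and 5 down. With the adipocyte marker covariate cortex had 154, 198, 391, 279 and 182, and medulla 32 at 1.3 MBq. At 14 MBq this covariate turned the balance in medulla to 173 up and 203 down.

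Leaving out each array in turn gave 10 to 157 genes in cortex at 1.3 MBq, 13 to 431 at 3.6, 14 MBq 24 to 348, 45 MBq 21 to 349 and 140 MBq 49 to 149. It gave 47 to 353 among the cortex groups and 45 to 90 in the cortex trend. In medulla the ranges were 5 to 425 at 1.3 MBq, 52 to 711 at 3.6, 65 to 871 at 14, 67 to 817 at 45 and 74 to 296 at 140 MBq, with 230 to 992 among the groups and 65 to 90 in the trend. Between tissues the range was 21 to 71, and the interaction stayed at 0 throughout.

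Against 192 list calls, an estimated correlation gave 17, fry 77 and the deposited normalisation 199, of which 17, 76 and 189 were among the 192. Of 168 list calls against the controls, 121 were kept without control replicate 1. The direction of camera's test then turned for 2 lists at 140 MBq in medulla, with medians of 0.0291 for interferon-stimulated genes and 0.0448 for proximal tubule markers, and neither was called. The median of MHC genes in medulla at 1.3 MBq turned from -0.59 to 0.02 and that call ended. Of 148 calls of genes named by the rule, where a gene counts once for each comparison, 137 were kept with the deposited normalisation and 131 with the block, and of 119 tested without control replicate 1, 63 kept it and 56 lost it. Left out in turn, at least 1 array ended 76 of the 148.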

Other observations

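Several tests in this part were chosen after the results had been seen: those of control replicate 1 (and then its requirement on the quartiles, without which that array would have been taken as the source) and of immune cell loss for the immune lists, all 3 for the clock and fatty acid lists, and those of cortex tissue (and then its reading of distal tubule markers) and of a single array at 14 MBq. Earlier forms for the clock and fatty acid lists (0.920 without control replicate 1 and 0.909 for brightness) and for a single array (0.976) were set aside, because they ran on genes called with every array included. The genes named in this part were also chosen after their values were seen. Mmp2, a gelatinase that degrades basement membrane collagen, rose at 140 MBq by 2.18 ± 0.35, adjusted p = 0.00538 in cortex and by 1.94 ± 0.34, adjusted p = 0.00721 in medulla, and per doubling of activity by 0.29 ± 0.06 and 0.30 ± 0.05. Rgs5, a regulator of G protein signalling known from pericytes, rose at 140 MBq by 1.13 ± 0.25 in cortex and 1.06 ± 0.20 in medulla. The smooth muscle and pericyte list, of which Rgs5 is a member, lay at 0.61, 0.08 and 1.91 on the cortex arrays at 140 MBq and at 0.04, -0.11 and -0.41 on the cortex controls, and in medulla at -0.07, -0.09 and -0.04 against -0.06, -0.15 and -0.20. The apoptosome gene Apaf1 rose per doubling by 0.19 ± 0.03, adjusted p = 0.00357 in cortex and 0.20 ± 0.03, adjusted p = 0.00517 in medulla. Slc8a1, a sodium-calcium exchanger, had slopes of -0.14 ± 0.03 and -0.15 ± 0.03.

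In medulla at 14 MBq heat shock genes lay higher: of 13 measured, 3 rose, Hspa4l (1.38 ± 0.34), Hspb1 (0.98 ± 0.24) and Hsp90aa1 (1.65 ± 0.45), and adjusted over the list alone 5 rose and 1 fell (camera, adjusted p = 0.0248, and adjusted p = 0.385 with an estimated correlation). The adrenal marker list lay 5.54 above its mean over the 36 arrays on cortex 14 MBq replicate 3 and 4.74 on medulla 14 MBq replicate 3. Without these arrays the counts at 14 MBq were 348 in cortex and 65 in medulla.

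Interferon, MHC and myeloid lists had medians below 0 at every activity in both tissues. Array brightness as the source is argued against, since with the log2 median signal as a covariate the list medians kept a median ratio of 0.817 (quartiles 0.759 to 0.924), except for interferon genes at 140 MBq, where it stays open as the median went from -0.50 to -0.21 in cortex and from -0.41 to -0.13 in medulla. Control replicate 1 alone leaves part of the pattern: without it the median ratio was 0.479 (quartiles 0.358 to 0.557, over 30 list medians), and camera still called each list at 3.6, 14 and 45 MBq in both tissues but none at 140 MBq, while with an estimated correlation none of these lists was called even with that array, so its share stays open. Control replicate 2 also lay high in these lists (0.63, 1.00 and 0.74 in cortex and 0.43, 0.81 and 1.51 in medulla) and control replicate 3 did not (-0.20, -0.29 and -0.20, and -0.02 and -0.14), except for the medulla myeloid list, where it lay at 0.40, above all 6 medulla arrays at 14 and 45 MBq. A loss of immune cells with activity also stays open, because 0 of 6 list trends over the treated arrays were called downward with an estimated correlation and none upward, although the trends were positive for interferon genes (medians 0.0370 and 0.0438; camera, adjusted p = 0.0136 and 1.96e-05, and adjusted p = 0.729 and 0.441 with an estimated correlation), negative for MHC genes (-0.0643 and -0.0369; camera, adjusted p = 0.0136 and 0.0847, and adjusted p = 0.741 and 0.685 with an estimated correlation) and of both signs for myeloid markers (-0.0106 and 0.0462; camera, adjusted p = 0.880 and 0.284), and medians against the controls were smaller in size at 140 than at 45 MBq (cortex myeloid -0.46 against -1.58).

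Camera called the clock and fatty acid lists at every activity in both tissues, but with an estimated correlation 1 of 11 clock calls and 1 of 12 fatty acid calls held, trends included, and no fatty acid gene was among the 21 medulla genes called at all 5 activities. Control replicate 1 alone is argued against as the source of the list shifts, with a median ratio of list medians of 0.922 without it (quartiles 0.813 to 0.977, over 20 list medians), and so is array brightness, with 0.871 (quartiles 0.779 to 0.923). Chance values of simulated shared controls gave 0 of 200 draws with any gene called at all 5 activities. The draws took their controls from the residuals of all groups, so they cannot exclude deviations of these particular controls. A difference in time of day or in feeding between control and treated mice is a possible explanation, and it was not tested, as no such times are given in the sources used here.

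Medulla had 474 called genes at 14 MBq, more than at the other activities, but 51 against 53 at 45 and 57 at 140 MBq with the stricter call, and 94 against 101 at 140 MBq without control replicate 1. Cortex tissue in the medulla pieces stays open: the called genes had a median ratio of cortex to medulla changes of 0.843 (quartiles 0.633 to 1.07, over 469 genes), where cortex tissue would give a low one, but distal convoluted and connecting tubule markers were higher on the 3 arrays (0.0894, 0.235 and 0.163) than on the other 15 (at most -0.0364). A single 14 MBq array stays open. Genes called without it had a lowest median ratio on it to the other 2 of 0.819 (quartiles 0.688 to 1.05, over 114 genes). Both changes use the same controls, so this cannot decide. Without each in turn 109, 133 and 65 were called. Adipose tissue stays open. With its marker covariate the median ratio was 1.03 (quartiles 0.945 to 1.12), but rises went from 263 to 173 (falls 211 to 203). A biological response also stays open, untested.

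Other splits of the same arrays were also counted. For the 3 against 3 comparisons there are 10 splits, too few for a share under 0.05. In cortex 1 of 10 splits called as many genes as the real one at 1.3 MBq (36 genes, highest other 1), 2 at 3.6 MBq (47, highest other 67), and 1 each at 14 MBq (148, 7), 45 MBq (107, 0) and 140 MBq (105, 0). In medulla it was 1 of 10 at each activity, with 85, 207, 474, 250 and 165 genes and highest others of 4, 28, 0, 0 and 0. Between tissues 4 of 10 splits called as many as the real 44, the highest 413, from a split that keeps a same-numbered pair together on each side. Of the 4 splits that part all pairs, the 3 other than the real one called 0. For any difference among the groups, 2 of 100 splits in cortex (78, highest other 217) and 1 of 100 in medulla (561, 3) called as many. Both shares lie under 0.05. The splits treat all arrays as independent samples, which the labels do not state, so chance is not excluded. The trends gave 3 of 100 in cortex (78, highest other 625, which points to a structure of the samples that was not examined) and 1 of 100 in medulla (88, 1). For the interaction the real count was 0, which all 100 splits reach whatever the data (highest other 7), so this count says nothing about chance.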
